A study of Mus musculus with 16 samples.

How the data were processed

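Gene expression was measured by RNA-seq in cortical parvalbumin (PV) interneurons sorted from adult mice. Per the labels' protocols, brain tissue was digested with pronase, fixed for 15 min in 4% paraformaldehyde and triturated, and nucleated cells (DRAQ5 positive) with green fluorescence were collected by flow cytometry. Fixed RNA was freed with proteinase K, polyA-selected and sequenced as 150-bp read pairs, per the labels. Mice were 113.1 ± 11.6 days old over the whole study; no age, sex, litter or batch is given per library in the sources used here. The labels put 9 libraries in the eGFP group and 7 in the eGFP-GluA2 group and number them as biological replicates.

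Per the series' design text, the authors processed the reads with bcbio-nextgen 1.2.3, aligned them to GRCm38 with STAR, quantified genes with Sailfish on the Ensembl annotation and compared the groups with DESeq2. The deposited table of counts holds whole numbers of reads for 54532 genes and is not normalized; which counter made it is not given in the sources used here. The deposited TPM values are a second table by the authors, scaled for transcript length. The third deposited table holds signal values, which are gene counts divided by a size factor per library, beside the authors' log2 fold change with its standard error, a test statistic (a score), p-values and adjusted p-values. Of these normalized values 100% were whole multiples of the value of a single read in their library, within a tolerance of 0.001. Reads recovered in this way came to 10477517 to 17382059 per library and differ from the deposited counts, so both were tested. Whether counting used strand is not given, so reads in the shared part of overlapping or antisense genes cannot be assigned.

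The tables were read by gene identifier, and 54409 identifiers were named from GENCODE M21 on GRCm38, the authors' build; 123 were not named there. Coordinates are 1-based on GRCm38. Total counts ran from 7454165 to 15462544 per library. The main test used edgeR 4.0.16 on the deposited counts: TMM scaling, filterByExpr with the group, and the quasi-likelihood F test with robust dispersion, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter kept 26257 genes, which held 99.2% of all counts, and removed 28275. Standard errors of log2 fold changes were taken from the F statistic, and intervals are 95% intervals from the same fit. Values per library are log2 CPM with a prior count of 2, or CPM as mean ± SD.

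Single values (Gria2 level and share, cell-type marker means, library measures) were compared by exact two-sided permutation tests over all assignments of 16 libraries to groups of 9 and 7. The Gria2 share is the percent of the summed TPM of Gria1 to Gria4. In all, 37 gene lists (815 members, all found in the tables) were fixed before the data were examined: 21 on receptors, synapses, channels, calcium, activity, PV identity and metabolism, 11 of markers of other cell types and 5 technical. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry as companions. The named genes followed a rule set before the data were examined. They are Gria1 to Gria4 and Pvalb. They are also the genes past the threshold with an average log2 CPM of at least 2, up to 10 per direction. For each list of interest they are the members past the threshold, up to 4, or, where none passed, the 2 members of smallest p as values only. For each discussed list of cell types or technical genes they are the 2 most abundant members and the 2 of smallest p. Some genes that the rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

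Alternatives chosen before the data were examined were DESeq2 1.42.0, other scalings, filters and thresholds, limma-voom, limma on log2(TPM + 0.5) with other pseudocounts, a block for the replicate number, 1 surrogate variable from svaseq (sva 3.50.0), marker-list and Xist covariates, and leaving out each library. Added after seeing the data were fits with a background measure. This measure is the CPM of 1448 autosomal olfactory and vomeronasal receptor genes, used as a log2 covariate or as 3 tiers of libraries (under 500, 500 to 1500 and over 1500 CPM). Also added were fits without some tiers, on recovered reads and on protein-coding genes. Exact permutation tests within tiers used all 1500 assignments that keep the group sizes of each tier. Other analyses used R 4.3.3, Python 3.11.15 and scipy 1.17.1.

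The gene tests were tested on simulated data for the comparison of eGFP-GluA2 with eGFP. Counts were drawn from the real means, library sizes and dispersions of 24947 to 25530 tested genes, with 200 genes changed, in 3 simulations. With the libraries' background gradient in the simulated means, the test without covariates called 5.97% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 66.7% of those changed 4-fold. With 1 surrogate variable these shares were 38.8%, 76.1% and 87.9%. Without the gradient the test without covariates called 44.8%, 82.1% and 96.0%. With the gradient at most 2 unchanged genes were called in any simulation. Without it up to 14 were called with 1 surrogate variable and up to 9 without covariates or with the background level. The simulated gradient was built from the log2 background level, which is itself the covariate, so fits that model it were favoured. These false calls do not carry over to the real libraries. There, splits into arbitrary groups gave up to 5691 genes with 1 surrogate variable and 6376 with the background level. No gene list was called with or without the gradient, though simulated genes vary independently of each other.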

Results

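PV interneurons are fast-spiking GABAergic cells of the cortex. Their AMPA receptors are often permeable to calcium because they hold little of the GluA2 subunit, which in its edited form blocks calcium. Per the labels, the mice expressed in PV cells either eGFP, the control, or eGFP fused to GluA2, in order to test what the removal of calcium-permeable AMPA receptors does. The data are read counts per gene in 16 libraries of sorted cells, 9 eGFP and 7 eGFP-GluA2. Each library held 7454165 to 15462544 counts, and 26257 genes were tested.

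The libraries differed most along an axis that did not follow the group. The first principal component of log2 CPM held 84.0% of the variance and separated the libraries by their reads in olfactory and vomeronasal receptor genes, which serve in sensory neurons of the nose. These reads ranged from 82.4 to 4142 CPM and are called the background below. In 6 libraries (4 eGFP, 2 eGFP-GluA2) the background was high, at 1909 to 4142 CPM. In 5 libraries (2 eGFP, 3 eGFP-GluA2) it was in the middle, at 675 to 1276 CPM. In the other 5 (3 eGFP, 2 eGFP-GluA2) it was low, at 82.4 to 162 CPM. By replicate number, eGFP replicates 1 to 4 were high, 5 and 6 middle and 7 to 9 low. Of the eGFP-GluA2 replicates, 1 and 3 were high, 2, 4 and 5 middle and 6 and 7 low. Background thus went with replicate number in both groups, apart from eGFP-GluA2 replicate 2. Whether the numbers follow an order or batch of processing was not tested, since no batch is given per library. Genes with at least 1 read numbered 30087 to 33334 in the low-background libraries and 47975 to 49971 in the high-background ones. Pvalb, which encodes parvalbumin, averaged log2 CPM 8.63 ± 0.20 (SD, n = 5) in the low-background and 7.13 ± 0.49 (SD, n = 6) in the high-background libraries. The groups did not differ in background (log2 CPM 9.58 ± 2.18, SD, n = 9, in eGFP and 9.41 ± 2.21, SD, n = 7, in eGFP-GluA2; exact permutation p = 0.875).

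**Figure D1:**
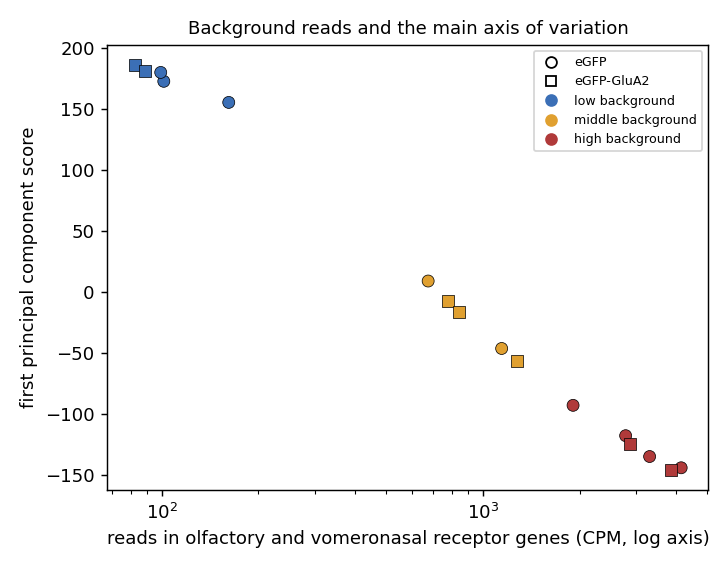
Score on the first principal component of log2 CPM (vertical axis) against reads in olfactory and vomeronasal receptor genes (horizontal axis, CPM, log axis) for 16 libraries, circles for eGFP and squares for eGFP-GluA2. Colours mark low, middle and high background; each colour holds libraries of both groups, and the score was 155 to 186 in low-background and -146 to -92.8 in high-background libraries.

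Gria2, the gene of the GluA2 subunit (ENSMUSG00000033981, chromosome 3: 80681450 to 80802835, minus strand), was higher in eGFP-GluA2 cells. Its level was 963 ± 215 CPM (SD, n = 7) against 587 ± 111 CPM (SD, n = 9) in eGFP cells. Reads of the fusion transgene and of the endogenous gene are counted together here. The log2 fold change was 0.71 ± 0.16 on counts (SE; 95% interval 0.37 to 1.05). It was larger on TPM, at 1.11 in limma on log2(TPM + 0.5) (adjusted p = 0.0829), and on reads recovered from the authors' normalized counts, at 1.04 (edgeR adjusted p = 0.0217). On log2 CPM the exact two-sided permutation test gave p = 0.000699, and 5 of 7 eGFP-GluA2 libraries lay above every eGFP library. Within the background tiers the groups did not overlap. The difference was 0.74 in the low-background, 0.75 in the middle and 0.54 in the high-background libraries, and the exact permutation within tiers gave p = 0.000667, the smallest it can give. In edgeR's quasi-likelihood test without covariates, however, the adjusted p of Gria2 was 1.00. It passed the same threshold with the background level as a covariate (0.69 ± 0.11, adjusted p = 0.0145), with 1 surrogate variable (0.70 ± 0.12, adjusted p = 0.0208) and with DESeq2 (0.70, adjusted p = 0.0157), and over all alternatives its adjusted p ran from 6.63e-27 to 1.00.

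The other AMPA receptor subunits gave no such difference on counts over all libraries. The log2 fold change was 0.17 ± 0.21 for Gria1, 0.06 ± 0.18 for Gria3 and 0.08 ± 0.18 for Gria4 (SE), each with an adjusted p of 1.00 in edgeR. In log2 CPM they differed by 0.18, 0.15 and 0.15 in low-background libraries (3 eGFP, 2 eGFP-GluA2), without overlap, and by -0.01, -0.06 and -0.17 in high-background ones. With so few libraries a lack of overlap is easily reached by chance. Pvalb had none in the low-background libraries either, at a difference of -0.27. On TPM Gria1 averaged 97.1 against 78.1 (exact permutation p = 0.141, and 0.00733 within tiers). It was at 155 and 130 in eGFP-GluA2 replicates 6 and 7. The other eGFP-GluA2 libraries, at 69.5 to 83.9, lay within the eGFP range of 58.8 to 101. For Gria3 and Gria4 on TPM the exact permutation within tiers gave p = 0.08 and 0.0533. Their TPM were also highest in eGFP-GluA2 replicates 6 and 7. Gria2 made up 45.1% ± 2.16 (SD, n = 7) of the summed TPM of Gria1 to Gria4 in eGFP-GluA2 cells and 30.7% ± 3.37 (SD, n = 9) in eGFP cells. Each of 7 eGFP-GluA2 libraries exceeded every eGFP library (exact permutation p = 8.74e-05, the smallest the assignments can give). The shares of the other 3 subunits were lower: Gria1 held 23.2% against 28.1%, Gria3 14.4% against 18.8% and Gria4 17.3% against 22.4%. These 4 shares sum to 100%, so they are not independent of each other. In deposited counts instead of TPM, the Gria2 share was 39.7% ± 2.41 against 30.6% ± 3.32.

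**Figure D2:**
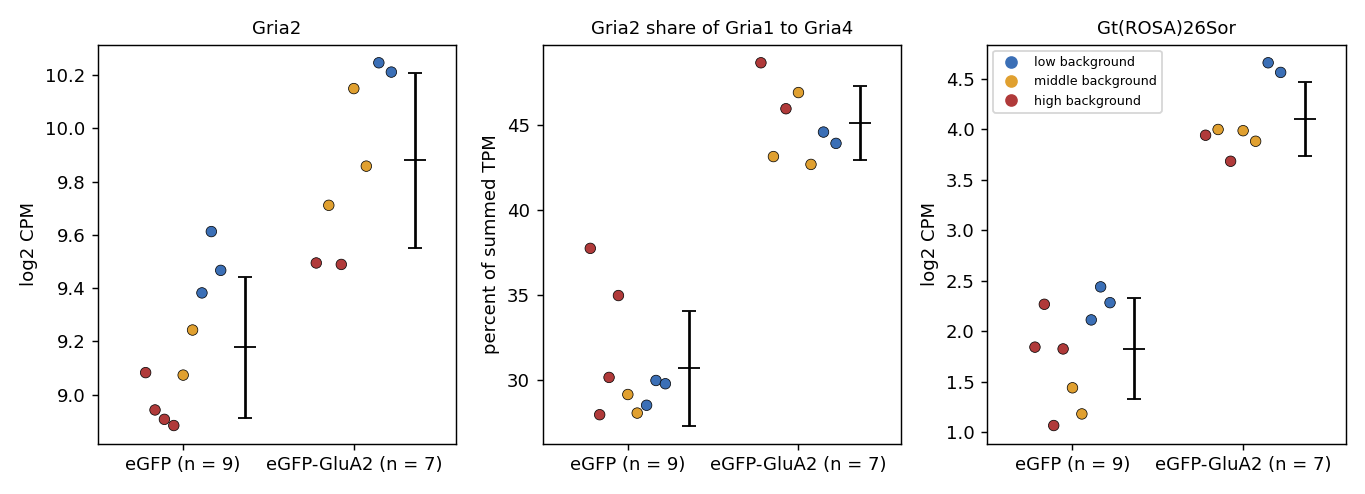
Gria2 level (log2 CPM), Gria2 share of the summed TPM of Gria1 to Gria4 (percent) and Gt(ROSA)26Sor level (log2 CPM) in each library, coloured by background, for 9 eGFP and 7 eGFP-GluA2 libraries. Bars give the mean ± SD; the Gria2 share averaged 30.7% in eGFP and 45.1% in eGFP-GluA2 libraries, with no overlap.

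Over all genes, 1 of 26257 passed, Gt(ROSA)26Sor (ENSMUSG00000086429, chromosome 6: 113067428 to 113077333, minus strand), a noncoding RNA of the Rosa26 locus, which is widely used for transgene insertion. Its log2 CPM was 4.10 ± 0.36 (SD, n = 7) in eGFP-GluA2 and 1.83 ± 0.50 (SD, n = 9) in eGFP cells. The log2 fold change was 2.30 ± 0.22 (SE; edgeR adjusted p = 0.000245), and 7 of 7 eGFP-GluA2 libraries lay above every eGFP library. Its annotation overlaps Thumpd3 on the other strand (113046225 to 113068273), and reads in the part they share cannot be assigned without strand. At an unadjusted p under 0.05 there were 293 genes, 1.12% of those tested. With no difference between the groups, a calibrated test would on average put a share of 0.05 of the genes there. The test without covariates thus gave fewer small p-values than chance alone would. With 1 surrogate variable as a covariate 995 genes lay under this p, and with the background level 999. The low share and the high adjusted p of single genes therefore do not show that few genes differ. In the authors' deposited table an adjusted p under 0.05 was reached by 9 genes, 4 of them higher, among them Gt(ROSA)26Sor (log2 fold change 1.38) and Gria2 (0.85). Whether these deposited fold changes were shrunk is not given in the sources used here, so their size cannot be set against that of edgeR's.

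With 1 surrogate variable as a covariate, 10 genes passed, 4 higher and 6 lower; 9 of these passed with the background level as a covariate. They are named here after their values were seen. Besides Gt(ROSA)26Sor and Gria2, the genes higher in eGFP-GluA2 cells were Eps8 (log2 fold change 0.81 ± 0.14, adjusted p = 0.0166), which codes for an actin-capping and bundling protein, and Whrn (0.61 ± 0.12, adjusted p = 0.0433), which codes for the scaffold protein whirlin. The genes lower in eGFP-GluA2 cells included the neighbouring transporter genes Abca9 (-0.80 ± 0.11, adjusted p = 0.000774) and Abca6 (-0.73 ± 0.12, adjusted p = 0.00895). P3h4, whose product takes part in collagen modification, was also lower (-0.73 ± 0.12, adjusted p = 0.0153). The remaining lower genes were Gm11592, Gm11702 and Gm43900, with log2 fold changes of -2.23 ± 0.27, -1.84 ± 0.32 and -1.22 ± 0.23. Gm11592 overlaps Npepps in part, on the other strand, and Gm11702 is a processed pseudogene inside Grb2, so their counts are uncertain; Gm11702 is listed at 0 in the authors' deposited table. Besides Gt(ROSA)26Sor and Gria2, 5 of the genes lie on chromosome 11, between 97280128 (Gm11592) and 115657559 (Gm11702), 2 on chromosome 6 (Gm43900 from 80827138, Eps8 from 137477245) and Whrn on chromosome 4 (from 63414910). Gm43900 is the gene that missed the threshold with the background level as a covariate (adjusted p = 0.0786). In log2 CPM the groups were without overlap for 3 of the 10 genes, Gt(ROSA)26Sor, Gm11592 and Gm11702. In the authors' deposited table Abca6 and P3h4 passed as well. Abca9, Eps8, Whrn and Gm43900 did not pass there, nor did Gm11592 (adjusted p = 0.0527).

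Gene lists were compared next. In camera with its preset correlation 11 of 37 lists passed, 10 higher and 1 lower in eGFP-GluA2 cells. With an estimated correlation 1 list passed, the excitatory neuron markers, of which 18 of 22 were above 0 in the same libraries (median log2 fold change 0.24). Leaving out single libraries gave 6 to 22 lists by the preset correlation. Without each single library in turn 5 of the 11 lists passed (AMPA subunits, AMPA auxiliary proteins, activity-regulated genes, excitatory neuron markers and erythrocyte genes), while 14 of the 26 lists that had not passed did so without at least 1 of the libraries. With the background level as a covariate 5 lists passed: AMPA subunits, AMPA auxiliary proteins, activity-regulated genes, ribosomal proteins and excitatory neuron markers. The AMPA subunit list includes Gria2, whose counts hold reads of the transgene.

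Among glutamate receptors, all 4 AMPA subunits had log2 fold changes above 0 (median 0.12, camera adjusted p = 1.44e-05; adjusted p = 0.300 with an estimated correlation). None passed over all genes tested, and 1, Gria2, passed when adjusted over the list alone. Counts of Gria2 (0.71 ± 0.16) include reads of the transgene, while Gria1, Gria3 and Gria4 had 0.17 ± 0.21, 0.06 ± 0.18 and 0.08 ± 0.18. The list was not tested without Gria2, so its result does not show a rise of the other subunits. Of 27 AMPA receptor auxiliary proteins, 24 were above 0 (median 0.14, camera adjusted p = 1.87e-10; adjusted p = 0.300 with an estimated correlation). None passed over all genes, and 2 passed when adjusted over the list alone. These were Shisa8, an AMPA receptor-associated transmembrane protein (0.61 ± 0.14, 7.95 ± 1.25 against 5.21 ± 0.93 CPM), and Nptx1, a pentraxin that clusters AMPA receptors at synapses (0.46 ± 0.12, 22.4 ± 4.41 against 16.3 ± 2.04 CPM). Of 21 genes of NMDA, kainate and metabotropic glutamate receptors, 14 were above 0 (camera adjusted p = 0.0445; adjusted p = 0.605 with an estimated correlation). Grm7 and Grm4 had log2 fold changes of 0.27 ± 0.12 and 0.28 ± 0.18, and 0 members passed when adjusted over the list alone. In the same libraries Slc17a7, an excitatory neuron marker, had 0.58 ± 0.22.

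Activity-regulated genes, such as immediate early genes, were above 0 in 27 of 36 cases (median 0.12, camera adjusted p = 0.000226; adjusted p = 0.586 with an estimated correlation), and 0 passed when adjusted over the list alone. The members of smallest p were Pcsk1, a prohormone convertase, at 0.25 ± 0.13 and Ier2 at 0.33 ± 0.20. With the cell-type covariates, which include the excitatory neuron markers, the direction of the list turned (adjusted p = 0.472). Genes of the excitatory postsynapse were above 0 in 25 of 39 cases (camera adjusted p = 0.0176; adjusted p = 0.949 with an estimated correlation), with Lrfn4 at 0.22 ± 0.14 and Lrrtm4 at -0.16 ± 0.13. Presynaptic release genes were above 0 in 27 of 38 cases (camera adjusted p = 0.0496; adjusted p = 0.949 with an estimated correlation), with Sv2b, which is also on the list of excitatory neuron markers, at 0.40 ± 0.17 and Sv2c at 0.47 ± 0.29. With the background tiers as a block the direction of the presynaptic list turned (adjusted p = 0.904). Both lists had 0 members past the threshold adjusted over the list alone; with 1 surrogate variable or the background level as a covariate the presynaptic list had 1. These lists, like that of the NMDA, kainate and metabotropic receptors, no longer passed with the background level as a covariate (adjusted p = 0.304, 0.210 and 0.193).

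Markers of PV identity did not pass in the test without covariates, but this depended on the setting. Pvalb had 273 ± 102 CPM (SD, n = 7) in eGFP-GluA2 and 274 ± 136 CPM (SD, n = 9) in eGFP cells, a log2 fold change of -0.01 ± 0.34 (95% interval -0.73 to 0.72). Of 28 identity genes 17 were above 0 (camera adjusted p = 0.113; adjusted p = 0.949 with an estimated correlation), with Rbp4 at 0.22 ± 0.20 and the potassium channel gene Kcnc1 at 0.25 ± 0.23. The potassium channels of fast spiking gave the same adjusted p, 0.113, with 20 of 32 genes above 0 and Kcnc4 at 0.22 ± 0.23. Both lists passed, as higher, with no filter on low counts (0.0319 and 0.0285), with cell-type covariates (4.84e-05 and 0.000171) and without any 1 of eGFP replicates 6, 7, 8 and 9 and eGFP-GluA2 replicates 1 and 3, where the adjusted p was as low as 1.38e-05 and 0.000173. With upper-quartile scaling PV identity passed (0.0424). With the background level as a covariate they did not (0.687 and 0.579). The perineuronal net, the matrix around these cells, gave 0.360, with Nptx2 at 0.29 ± 0.21 and Ptprz1 at -0.17 ± 0.12. Adjusted over the list alone, 0 members of these 3 lists passed.

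Of 15 voltage-gated calcium channel genes, 10 were above 0 (camera adjusted p = 0.0289; adjusted p = 0.861 with an estimated correlation, and 0.265 with the background level as a covariate), and 0 passed when adjusted over the list alone. Cacna2d1, an auxiliary subunit, had 0.38 ± 0.15 and Cacna1h, a T-type channel, 0.21 ± 0.12. Calcium buffers, pumps and stores (37 genes, camera adjusted p = 0.159) had Ryr1 at 0.25 ± 0.13 and Micu2 at -0.19 ± 0.12. Calcium-dependent signalling genes (38 genes, 0.113) had Camk1g at 0.29 ± 0.17. The sodium channels (14 genes, 0.926) had Scn3b at -0.18 ± 0.09 and Scn9a at -0.19 ± 0.12; their median was above 0, at 0.03, while camera pointed lower. HCN and leak channels (17 genes, 0.328) had Hcn3 at 0.10 ± 0.10 and Kcnk2 at 0.10 ± 0.16. GABA-A receptor subunits (16 genes, 0.476) had Gabra5 at 0.16 ± 0.14. The list named GABA synthesis and release (12 genes, 0.360) had Gls2 at 0.12 ± 0.10. Slc12a5, which codes for a chloride transporter and is also on this list, had 0.16 ± 0.24. Without 1 or another of the 16 libraries, 5 of these lists passed: calcium-dependent signalling in 6 of 16 cases (adjusted p as low as 0.000173), calcium buffers, pumps and stores in 5 (0.00184), and HCN and leak channels (0.0213), GABA-A receptor subunits (0.0342) and GABA synthesis and release (0.00869) in 2 each. Adjusted over the list alone, 0 members of any of these lists passed.

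The other lists of interest did not pass without covariates either. Gap junction genes had a camera adjusted p of 0.224, with Panx1 at 0.16 ± 0.14 and Panx2 at 0.23 ± 0.27. Endoplasmic reticulum stress genes gave 0.499 (past the threshold without 1 or another library in 4 of 16 cases, as low as 0.00317), with Chac1 at 0.50 ± 0.36 and Ern1 at -0.17 ± 0.12. Nuclear genes of oxidative phosphorylation gave 0.508 (2.44e-06 without eGFP-GluA2 replicate 1, and 0.0202 in the other direction without eGFP replicate 1), with Atp5l at -0.12 ± 0.15 and Atp5g1 at 0.18 ± 0.29. RNA editing genes gave 0.745, with Adat1 at 0.09 ± 0.09 and Fxr1 at -0.11 ± 0.16, and polyamine genes gave 0.812, with Smox at 0.09 ± 0.08 and Sat2 at 0.14 ± 0.13. The medians of these last 2 lists, -0.02 and -0.03, lay below 0 while camera pointed higher. Adjusted over the list alone, 0 members of these 5 lists passed.

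Markers of excitatory neurons were higher in eGFP-GluA2 libraries. Of 22 markers 18 were above 0, with a median of 0.24 (camera adjusted p = 3.49e-11; adjusted p = 0.00578 with an estimated correlation). Slc17a7, the vesicular glutamate transporter of cortical excitatory cells, had 45.9 ± 14.7 CPM (SD, n = 7) against 30.7 ± 8.71 CPM (SD, n = 9), a log2 fold change of 0.58 ± 0.22. Nrn1 had 0.46 ± 0.17. The most abundant markers, Cux2 and Camk2a, had 0.05 ± 0.15 and 0.18 ± 0.18. None passed over all genes, and 0 passed when adjusted over the list alone, against 5 with 1 surrogate variable and 5 with the background level as a covariate. The mean log2 CPM of the markers was 3.36 ± 0.24 (SD, n = 7) against 3.08 ± 0.28 (SD, n = 9), with exact permutation p = 0.0557 and an adjusted p of 0.613 over 11 cell-type lists. Within background tiers the exact permutation p was 0.00400 and the adjusted p 0.0440.

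**Figure D3:**
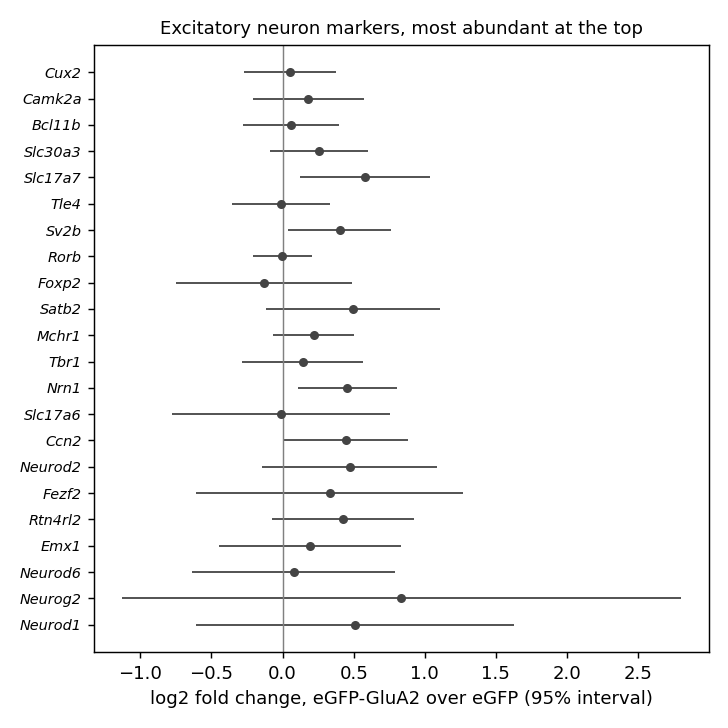
Log2 fold change of 22 excitatory neuron markers, eGFP-GluA2 over eGFP, from edgeR without covariates (points), with 95% intervals (lines), ordered by average log2 CPM. In all, 18 of 22 points lie above 0, Slc17a7 at 0.58 and Cux2 at 0.05.

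The mean level of none of the 11 cell-type lists passed the exact permutation test without tiers, and 0 had an unadjusted p under 0.05. Oligodendrocyte markers (11 of 18 above 0, median 0.14) passed in camera (adjusted p = 0.0303; adjusted p = 0.861 with an estimated correlation, and 0.0844 with the background level as a covariate), with Mbp at 0.23 ± 0.19, Ugt8a at 0.41 ± 0.21 and Cldn11 at 0.45 ± 0.33. The 4 tested erythrocyte genes were all below 0 (camera adjusted p = 0.00658; adjusted p = 0.239 with an estimated correlation, and 0.133 with the background level as a covariate), with Alas2 at -0.09 ± 0.10, Slc4a1 at -0.14 ± 0.88, Hbb-bs at -1.41 ± 0.55 and Hba-a1 at -0.99 ± 0.66. VIP, LAMP5 and SNCG interneuron markers gave 0.124; 1 of them, Lamp5, passed when adjusted over the list alone (0.51 ± 0.14), Cck and Npy had -0.18 ± 0.28 and 0.45 ± 0.27, and Reln had 145 ± 24.7 CPM against 146 ± 35.3 CPM. Camera adjusted p was 0.360 for microglia, 0.570 for thalamic and striatal markers, 0.673 for astrocytes and for endothelial and mural cells, 0.676 for fibroblast, ependymal and choroid cells, and 0.745 for SST interneurons and for oligodendrocyte precursors. Without 1 or another library the VIP, LAMP5 and SNCG markers passed in 1 of 16 cases, and the endothelial and mural markers in 1. For SST interneurons, astrocytes and endothelial cells the median was below 0 while camera pointed higher.

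Of the technical lists, the cytosolic ribosomal proteins were above 0 in 69 of 74 cases (median 0.10, camera adjusted p = 1.15e-05; adjusted p = 0.949 with an estimated correlation), with Rpl3 at 0.05 ± 0.25, Rpl4 at 0.07 ± 0.28, Rps16 at 0.29 ± 0.22 and Rpl21 at 0.31 ± 0.25. In the low-background libraries alone the direction of this list turned (adjusted p = 0.000309), and reads of these genes can be shared with their pseudogenes. Histone genes gave 0.159, heat shock genes 0.245, mitochondrially encoded genes 0.515 and sex-linked genes 0.952; without 1 or another library histone genes passed in 5 of 16 cases, heat shock genes in 3 and mitochondrially encoded genes in 2. Library measures did not differ between groups in exact permutation tests, and 0 of 5 had an unadjusted p under 0.05. Total counts were 10512161 ± 3065568 (SD, n = 7) in eGFP-GluA2 and 11249890 ± 2012129 (SD, n = 9) in eGFP libraries (exact permutation p = 0.562). Genes detected numbered 41535 ± 8136 and 42352 ± 8163 (exact permutation p = 0.826). Mitochondrial genes took 0.622% ± 0.285 and 0.600% ± 0.330 of counts (exact permutation p = 0.887). Ribosomal protein genes took 0.393% ± 0.0719 and 0.366% ± 0.0684 (exact permutation p = 0.449). The 100 most abundant genes took 24.0% ± 3.19 and 24.5% ± 2.28 (exact permutation p = 0.742). The adjusted p was 0.887 for each of these 5 measures.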

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

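Of 182 sets of values (a group's libraries for 1 gene or marker mean), 7 held a library far from the others of its group, where chance gives about 1 in 20, or 9.1. In the eGFP group, the mean log2 CPM of erythrocyte genes was 0.42 in replicate 7, next to 1.66 in the nearest library. Smox was at log2 CPM 3.88 in eGFP replicate 2 (nearest 4.21), and Ugt8a at 1.91 in eGFP replicate 1 (nearest 2.58). In the eGFP-GluA2 group, Chac1 was at 5.51 in replicate 4 (nearest 3.68) and Gm11592 at -1.87 in replicate 7 (nearest -0.77). In eGFP-GluA2 replicate 1, Rps16 was at 4.00 (nearest 4.78) and Whrn at 5.25 (nearest 5.70). With fewer such libraries than chance gives, no explanation was tested for them.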

How the results depend on the processing

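All results with the background level or tiers, without or within some tiers, on recovered reads or on protein-coding genes come from alternatives chosen after seeing the data. Gt(ROSA)26Sor passed in every alternative that tested it and without any single library. The count of 1 gene became 8 with DESeq2, 7 with the replicate block, 10 with 1 surrogate variable and 2 with each of upper-quartile scaling, a filter of 50 counts in 7 libraries, limma-voom, cell-type covariates and limma on log2(TPM + 0.5), with pseudocounts of 0.1 and 1 and with no filter. It became 9 with the background level as a covariate, 11 with the tiers as a block, 3 without the 6 high-background libraries, 154 in the low-background libraries alone, 3 on recovered reads, 5 on recovered reads with the background level, 26 with DESeq2 and the background level, and 6 among protein-coding genes with the background level, which leave out Gt(ROSA)26Sor. It was 1 without any single library. In simulated data the background gradient lowered the share of 1.5-fold changes called without covariates from 44.8% to 5.97%, against 38.8% with 1 surrogate variable and 40.3% with the background level, so the gradient can lower the count; for the other alternatives the cause was not tested.

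The log2 fold change of Gria2 was above 0 in every alternative. It passed at 0.70 with DESeq2, 0.69 with upper-quartile scaling, 0.69 with a filter of 50 counts, 0.79 with limma-voom, 0.70 with 1 surrogate variable, 0.69 with the background level, 0.67 with the tiers as a block, 0.78 in low-background libraries alone, 1.04 on recovered reads, 1.01 on these with the background level, 0.67 with DESeq2 and the background level and 0.68 among protein-coding genes with the background level. In limma on log2(TPM + 0.5), with pseudocounts of 0.1 and 1 and with no filter, it was 1.11, 1.12, 1.11 and 1.11 and did not pass (adjusted p 0.0792 to 0.0934). Without single libraries it was 0.65 to 0.77 and did not pass (adjusted p 0.531 to 1.00). The difference in Gria2 share passed throughout, at 9.16 points on counts, 14.2 with the replicate block, 15.0 within tiers and 13.8 to 15.3 points without single libraries.

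The 11 gene lists became 6 with a filter of 50 counts, 23 with the replicate block, 17 with cell-type covariates, 7 on recovered reads, 1 with an estimated correlation and 0 with fry (1 at an unadjusted p under 0.05). They became 5 with 1 surrogate variable and 5 in each of the fits with the background level, on deposited counts, recovered reads and protein-coding genes. Without single libraries the count was 6 to 22: 7 without eGFP replicate 1, 6 without eGFP replicate 3, eGFP replicate 4 or eGFP-GluA2 replicate 7, 19 without eGFP replicate 9, and 22 without eGFP-GluA2 replicate 1 or 3. Of 26 lists that had not passed, 21 did in at least 1 alternative; with the replicate block PV identity (2.82e-07) and fast-spiking potassium channels (5.59e-06) were among them. Directions of lists turned for sodium channels with the replicate block (adjusted p = 0.00432) and with cell-type covariates (0.0267), for activity-regulated genes with cell-type covariates (0.472) and for presynaptic genes with the tiers as a block (0.904). They also turned for oxidative phosphorylation with the tiers as a block (6.18e-05), without high-background libraries (0.0128), in low-background libraries alone (1.65e-14) and without eGFP replicate 1 (0.0202). Over all single libraries left out, the adjusted p of this list ran from 2.44e-06 without eGFP-GluA2 replicate 1, in its first direction, to 0.786. In low-background libraries alone ribosomal (0.000309) and histone genes (0.00277) turned too, as did sex-linked genes with Xist as a covariate (0.000217). The cause was not tested.

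Of the cell-type marker means 0 passed, without any single library and with the replicate block as well, and 1 within tiers, the excitatory neuron markers. Of 1256 comparisons of a list with an alternative, 1030 kept direction and side of the threshold, 125 no longer passed, 90 passed newly and 11 turned. Background went with replicate number, but same numbers were not taken as pairs. The labels name nothing they share and not every number's libraries deviate together. The correlations of same-numbered deviations were 0.89, 0.63, 0.89, -0.03, 0.19, 0.21 and 0.90 for replicates 1 to 7, and 2 of 7 were highest with their own number.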

Other observations

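Fits with the background level or its tiers, all tests of where the background, the receptor reads and the marker reads come from, the random draws of gene positions and the test of excitatory markers against the background were chosen after the result was seen. Besides the genes described so far, the authors' deposited table puts 5 genes past an adjusted p of 0.05, named here after their values were seen. These are the authors' fold changes, and whether they were shrunk is not given in the sources used here. Dchs1, a large cadherin, had a log2 fold change of 0.24 and Rpl34-ps1, a pseudogene, 0.34. Tacr1, the receptor of substance P, had -0.55, Gm26825 -0.17 and Gm2427 -1.17.

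Of 100 splits of the 16 libraries into 9 and 7, the real one included, 4 gave as many genes as the real split without covariates (1 gene; highest other 5346). With 1 surrogate variable 3 of 100 did (10 genes, highest other 5691), and with the background level 3 of 100 (9 genes, highest other 6376). These 3 shares lie under the bound of 5 in 100 set for chance. With only 100 splits drawn, and some of them far above the real one, they do not exclude chance. For gene lists 71 of 100 splits gave as many as the real 11 (highest other 26), so chance cannot be excluded. With the background level most splits gave at least the real 5 lists (highest other 22), so chance cannot be excluded there either. Counts that far above the real one point to a structure of the samples, which the share of high-background libraries alone does not account for. Of 5 splits with 5 of the 6 high-background libraries in the smaller group, 2 gave more genes than the real split without covariates, 2 with 1 surrogate variable and 1 with the background level, while 3, 2 and 3 of them gave 0. With the background level 928 genes came from a split outside these 5.

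Background reads differed up to 4142 against 82.4 CPM between libraries of the same study, and markers of other cell types rose with them (mean log2 CPM of endothelial and mural markers 0.09 to 0.88 in low-background and 2.26 to 2.64 in high-background libraries). A difference between the genotypes is argued against by the presence of both groups in each of the 3 tiers (exact permutation p = 0.875). In high- and middle-background libraries, RNA from other cells as the source of the receptor reads is argued against by the X-linked ones, whose density over that on autosomal ones was at most 0.752 in 5 libraries with 100 CPM or more of Y-linked genes and 1.10 to 1.25 in the other 6 (exact permutation p = 0.00216; 95% intervals of single libraries reached 0.970 and 0.827), so that genomic DNA, with a single X in males, may be their source, as a hypothesis, with library batches untested. In a pool of 98 non-neuronal markers, RNA from other cells cannot be told apart from genomic DNA, since from low to high background they rose per kb of exon by a median of 2.13 times the rise of receptor genes (95% bootstrap interval 1.78 to 2.40, above 1 but including 2, the bound set for RNA) and equal coverage of both by genomic DNA was assumed; endothelial and mural markers alone exceeded that bound (2.64, interval 2.20 to 3.17), and the other 5 lists did not. The few receptor reads of the 5 low-background libraries had ratios of 0 to 0.141. Genomic DNA is argued against there by an upper 95% bound of 0.314 in the 2 libraries under 100 CPM of Y-linked genes. This bound covers counting error only. In all libraries the X-linked receptor reads lie in just 9 genes, and the intervals of these ratios do not cover variation between genes.

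Of 8 genes past the threshold with 1 surrogate variable besides Gria2 and Gt(ROSA)26Sor, 5 lie on chromosome 11 (P3h4, Abca9, Abca6, Gm11592 and Gm11702) and 2 on chromosome 6 (Eps8 and Gm43900). Of 100000 random draws, a share of 0.00046 put as many genes on 2 chromosomes, or 0.00181 when genes within 1 Mb count once (6 of 7 loci). Since this measure was picked after the positions were seen, it cannot decide against chance positions. DNA of another strain carried along with bred loci could place the genes on these chromosomes, but this cannot be told apart from other causes. With the background level as a covariate, genes at an unadjusted p under 0.01 were more frequent than expected on chromosome 6 (25 against 12.1, hypergeometric adjusted p = 0.00920). They were not detectably so on chromosome 11 (20 against 15.4, hypergeometric adjusted p = 0.658). Those on chromosome 6 lay a median of 24.1 Mb from Gt(ROSA)26Sor (one-sided permutation p = 0.0844 against other tested genes of the chromosome), and strains and insertion sites are not given in the labels.

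Excitatory neuron markers were higher in eGFP-GluA2 libraries. The fit with the background level kept 111% of their median log2 fold change, but it cannot decide whether background is their cause. Mean background was close in both groups (log2 CPM 9.41 in eGFP-GluA2 and 9.58 in eGFP libraries, exact permutation p = 0.875). This covariate could therefore move a difference between the groups only a little. RNA of excitatory neurons in the sorted cells may contribute, but the values do not set it apart from a change within PV cells. In the fit with the background level 86.4% of the markers were above 0, against 18 of 22 without covariates. The 5 most abundant had log2 fold changes of 0.04 to 0.56 in that fit. The gate selects for green fluorescence, but whether excitatory neurons or their free RNA passed it was not tested. Of the 22 markers 2, Camk2a and Sv2b, are held by other lists. A change of these genes within PV cells remains open and untested.

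The genes and libraries that follow were chosen after their values were seen. On chromosome 4, Fam205c (42868004 to 42874234) was at log2 CPM 3.92 to 5.29 in all 7 eGFP-GluA2 libraries and at 4.20 to 4.52 in eGFP replicates 5, 8 and 9, but at -0.74 to 1.81 in the other 6 eGFP libraries. Fam205a1 (42848071 to 42853888) was at 2.19 to 3.78 in eGFP-GluA2 libraries, 2.26 to 2.79 in eGFP replicates 5, 8 and 9 and 0.13 to 0.92 in the other 6. Y-linked genes reached 100 CPM in 8 libraries, 4 of each group. In eGFP replicate 2, Xist was at 268 CPM with 17.6 CPM of Y-linked genes, and in eGFP replicate 3, Y-linked genes were at 176 CPM with 27.7 CPM of Xist.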
